A study of Daphnia magna with 15 samples.

How the data were processed

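Whole neonates of the water flea Daphnia magna, 48 to 72 h old, were exposed for 24 h in 25 mL of medium to an anticancer drug or to medium alone, per the labels' protocols, and poly(A) RNA libraries were made from 320 ng of total RNA with a strand-marking kit. Of 15 libraries, 3 came from etoposide at 300 ng/L, 3 from imatinib mesylate at 2000 ng/L, 3 from cisplatin at 10 ng/L, 3 from an unexposed set named control A and 3 from an unexposed set named control B. The labels do not say which control set belongs to which drug, or whether the replicates were separate cultures, so p-values measure the spread between these libraries, which could be technical.

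The deposited table holds FPKM (fragments scaled to transcript length and to the size of the library) made by the authors, with 1 row per assembled transcript and 1 column per library. The submitters' processing notes name CASAVA 1.8.0, Trim Galore, TopHat2 2.0, Bowtie2 2.1, Cufflinks 2.2.1 and Cuffdiff, without settings. The genome build and any scaling between libraries are not given in the sources used here. The table lists 33982 transcripts in 18877 loci on 2545 scaffolds; 12134 loci hold 1 transcript. Positions are given as the deposited table gives them. The identifiers are those of the assembly, and 0 of them matched the 28335 genes of the reference table used here (assembly ASM2063170v1.1). The files do not pair the loci with gene names, so the 25 gene lists written before the data were examined could not be matched, no list was tested, and at most 2 loci that rose and 2 that fell are named per comparison by rule.

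FPKM were summed over the transcripts of each locus, a step chosen once the table was seen to list transcripts. The 18098 loci with a mean of at least 1 FPKM over the 15 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (mean-variance trend, all 5 groups as separate means with a shared estimate of the spread), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low loci. For each drug, the main count was of loci that passed against control A and against control B in the same direction. Named loci were those with the largest change among these whose 3 drug libraries all lay above or all below the 6 control libraries; where a drug had fewer than 5, those with the smallest p against the mean of the control sets were taken. Loci behind the smallest counts were chosen after their values were seen and are marked so.

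FPKM carry no read counts, but at low loci many values lie at steps of what 1 read is worth. Ratios to etoposide 2 at loci over 600 bp with 1 transcript and a median under 1 FPKM, for values from 0.02 to 6 FPKM and up to 10 reads, gave an estimate of the relative depth of the libraries with Python 3.11.15 and scipy 1.17.1. The settings were chosen after seeing the data, a first estimator was replaced because it failed on simulated steps, and any scaling by the authors is included in the ratio. At the estimate, 63.1% to 78.7% of the ratios lay on a ratio of whole reads within 0.02 on the log2 scale, against a median of 31.5% to 47.1% at other shifts, so not all values are whole reads. Of the values at these low loci, 8.6% were above 0 but under 0.001 FPKM. A shift by a factor of 2 (in cisplatin 3, by a smaller factor) fitted nearly as many ratios, or more in control A 1 (81.5% against 76%), control B 2 and control B 3. The choice between such shifts therefore rests on the distribution of reads assumed in the likelihood. With the other shift, control A 1 would be at 30.8%. Absolute depth is unknown, so no counting intervals are given. Very short loci carry most of the FPKM: 73 loci under 100 bp took 72.6% to 96.1% of a library's total, so totals of FPKM are no measure of depth.

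The test was run on simulated data with the real means and spread and 200 changed loci among 18098. With the shared spread it recovered 13.4% of 1.5-fold, 41.8% of 2-fold and 77.3% of 4-fold changes for etoposide against control A, with 6 false calls. For cisplatin against control B it recovered 4.48%, 43.3% and 80.3% of these sizes, with 2 false calls. With each group's own spread, unchanged loci gave 240 false calls for etoposide against control A, 161 for imatinib against control A and 11 for cisplatin against control B.

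Replicate numbers are shared between groups in the labels. Deviations from the group means of same-numbered cisplatin and control B libraries correlated across loci at 0.24, 0.21 and 0.5, all over 0.1. These were therefore taken as paired, from the data and not from the labels. Of the 10 group pairs, this was the single one to meet that rule. Deviations within a group cancel out at each locus, so these correlations are not independent, and a likeness of 1 pair raises the others. Differently numbered libraries were not compared in this way, so the pairing is an assumption. The alternatives fixed before the data were examined were another pseudocount, other filters, quantile normalization, median centring, a replicate block, robust variance, a 2-fold minimum, fits on the groups compared alone, the 6 controls as 1 group and leaving out each library. Library weights, loci of at least 500 bp, transcripts not summed and a paired fit of cisplatin and control B alone were added after seeing the data, as were the alternatives for the loci and transcripts chosen after their values were seen.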

Results

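RNA of whole Daphnia magna neonates was sequenced after 24 h at low concentrations of 3 anticancer drugs: etoposide, a topoisomerase II poison, imatinib mesylate, a tyrosine kinase inhibitor, and cisplatin, a platinum compound that crosslinks DNA. Each drug group and each of the control sets A and B had 3 libraries. The relative depth estimated from the FPKM steps was 65.5% to 103% of that of etoposide 2 in 14 libraries and 15.5% in control A 1. There 30.8%, a factor of 2 higher, placed at least as many ratios on whole reads. In control B 2 and control B 3, 51.4% and 49.7% also placed more ratios than the estimate. For the other libraries another shift placed nearly as many, so their estimates are not settled either. Control A 1 listed 1375 loci at 0, against 71 to 289 in the others. The median SD per locus within a group, on the log2(FPKM + 1) scale, was 0.384 in control A, 0.29 in etoposide, 0.226 in imatinib, 0.16 in control B and 0.152 in cisplatin.

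**Figure D1:**
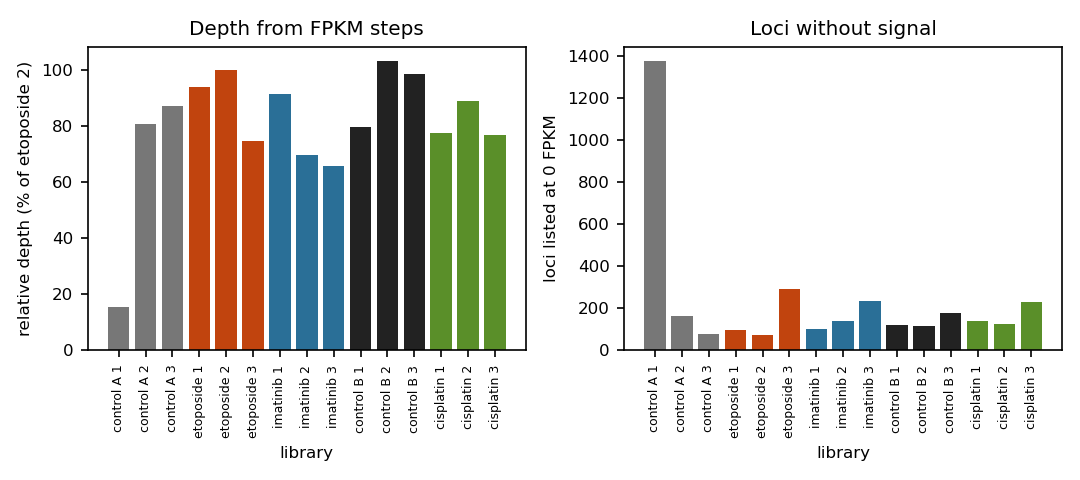
Estimated relative depth of each library as a percentage of etoposide 2 (left) and number of loci listed at 0 FPKM (right), 1 bar per library, coloured by group. Control A 1 stands at 15.5% and 1375 loci.

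The unexposed sets differed from each other in 4227 loci, 1175 higher and 3052 lower in control A than in control B (limma, adjusted p under 0.05). XLOC_002607 (scaffold00850, 2613 to 2800) had 2404, 125.9 and 409.9 FPKM in the control A libraries and was listed at 0 in all 3 control B libraries (limma, adjusted p = 0.0045). XLOC_002641 (scaffold00855, 15466 to 15703) had 1294 ± 1563 FPKM (SD, n = 3) in control A, with 90.53 FPKM in control B 1 and 0 in the other control B libraries (limma, adjusted p = 0.0249); it lost the call without control A 1, control B 2 or control B 3 (limma, adjusted p = 0.0685, 0.089 and 0.0957), in a fit of the control libraries alone (0.0731) and with library weights (0.113). XLOC_017629 (scaffold03233, 7028 to 7075) and XLOC_013530 (scaffold02249, 29929 to 29991) were lower in control A; both were listed at 0 in control A 1 and control A 2, and both are under 100 bp, where FPKM are unstable. XLOC_017629 lost the call without control A 1, control A 2 or any control B library (limma, adjusted p from 0.0532 to 0.0739), XLOC_013530 without control B 3 (0.053), and both in a fit of the control libraries alone (0.135 and 0.107). The median log2 difference of all loci was -0.24, an offset that median centring removes (etoposide and imatinib lay at -0.18 and -0.21 against control B, and at 0.02 each against control A), and 38.5% of loci had no overlap between the sets, against 10% by chance.
The direction depended on the scaling, with 1548 higher and 1651 lower after quantile normalization and 1805 higher and 1102 lower after median centring. The count was 1184 in a fit of the control libraries alone, and 2446, 2235 and 1863 without control B 1, 2 and 3.

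**Figure D2:**
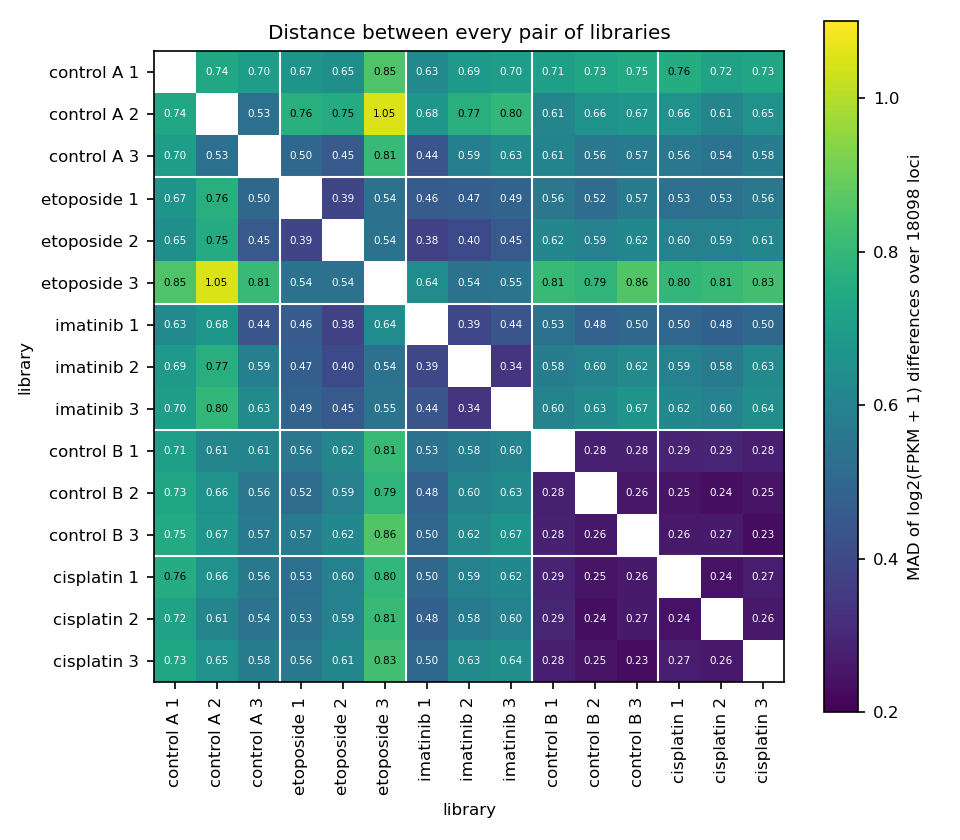
Median absolute deviation (MAD) of the log2(FPKM + 1) differences for every pair of the 15 libraries over 18098 loci; white lines part the groups. Pairs of a cisplatin and a control B library lie at 0.231 to 0.294, pairs within control A at 0.527 to 0.741.

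With etoposide, 1221 loci differed from both control sets, 218 higher and 1003 lower (limma, adjusted p under 0.05 in each comparison). The median fold was 1.87 for the loci that rose and 2.05 for those that fell. XLOC_013873 (scaffold02302, 14673 to 17349) rose from 4.142 ± 3.266 FPKM in control A and 7.327 ± 7.682 in control B to 62.86 ± 25.21 with etoposide (SD, n = 3), a log2 fold change of 3.66 against the mean of the sets (SE 0.683; limma, adjusted p = 0.0185 against control A and 0.00737 against control B). XLOC_013568 (scaffold02254, 8765 to 10968) rose to 27.03 ± 30.05 FPKM from 1.555 ± 2.178 and 0.7986 ± 0.7938, with 61.65 FPKM in etoposide 3 against 7.748 and 11.68 in the other libraries. XLOC_002493 (scaffold00835, 16570 to 16986) fell to 4.098 ± 3.13 FPKM from 33.27 ± 17.25 in control A and 29.35 ± 8.446 in control B, and XLOC_007580 (scaffold01456, 38037 to 38343) fell to 1.583 ± 2.743 from 11.55 ± 5.587 and 13.32 ± 1.858. With imatinib, XLOC_007580 measured 3.328 ± 1.167 FPKM, also below every control library.
Smaller and steadier changes stood beside these. XLOC_004708 (scaffold01117, 16768 to 22940) measured 71.5, 77.5 and 59.5 FPKM with etoposide, against 161 ± 27.1 in control A and 138 ± 7.7 in control B (SD, n = 3), which is 2.28-fold and 1.98-fold lower (limma, adjusted p = 0.00936 and 0.00125). XLOC_007968 (scaffold01517, 14201 to 19304) measured 6.16 ± 1.07 FPKM against 15.8 ± 1.59 and 13.8 ± 1.27. With imatinib, XLOC_004708 measured 101 ± 14.3 FPKM and XLOC_007968 7.59 ± 1.29, also below every control library, so these lower values are not particular to etoposide. Both were chosen after their values were seen, as the 2 of the 1221 loci that passed with any of the 9 libraries left out in turn; neither passed against both sets in a fit of the 9 libraries alone (limma, adjusted p = 0.102 for each) or with library weights (limma, adjusted p = 0.0678 for each).
Over all loci tested, 12.7% had etoposide values that did not overlap those of the 6 controls, against 2.38% by chance. That chance value takes the 9 libraries as interchangeable, although the control sets differed from each other. A group set apart for another reason than the drug could also exceed it. Against control A alone, 2797 loci passed, 1381 higher and 1416 lower; against control B alone, 5193 did, 1317 higher and 3876 lower, or 1951 and 2624 after quantile normalization and 2367 and 1947 after median centring. The loci that passed against both sets were 352 higher and 806 lower after quantile normalization and 425 and 667 after median centring.
Most calls against control A and against both sets ended in smaller fits, while etoposide fitted with control B alone gave 4516 loci. Fitted with control A alone, 1 locus passed, with 2999 at an unadjusted p under 0.05 where 905 are expected. That fit has 4 residual degrees of freedom against 10, and a median residual SD 1.24 times the shared one. No locus passed against both sets, a count of 0, when the fit held the 9 libraries compared. The 1221 loci became 3 without etoposide 3, 6 without control A 2, and 792, 707 and 665 without control B 1, 2 and 3; the 2797 became 7 and 11 without etoposide 3 and control A 2, and the 5193 became 3274 without etoposide 3 and 3057 without control B 3. XLOC_013873, XLOC_013568, XLOC_002493 and XLOC_007580 each lost the call without etoposide 3 and without control A 2, while the fold changes stayed large. Without control A 2 the log2 values were 3.29, 3.29, -2.66 and -2.69, with adjusted p from 0.0711 to 0.0869 (limma). Without etoposide 3 they were 3.38, 2.52, -2.17 and -2.42, with adjusted p from 0.0748 to 0.0949 (limma). With library weights these 4 loci lost the call too (limma, adjusted p from 0.0835 to 0.135), and 0 loci passed against both sets.

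**Figure D3:**
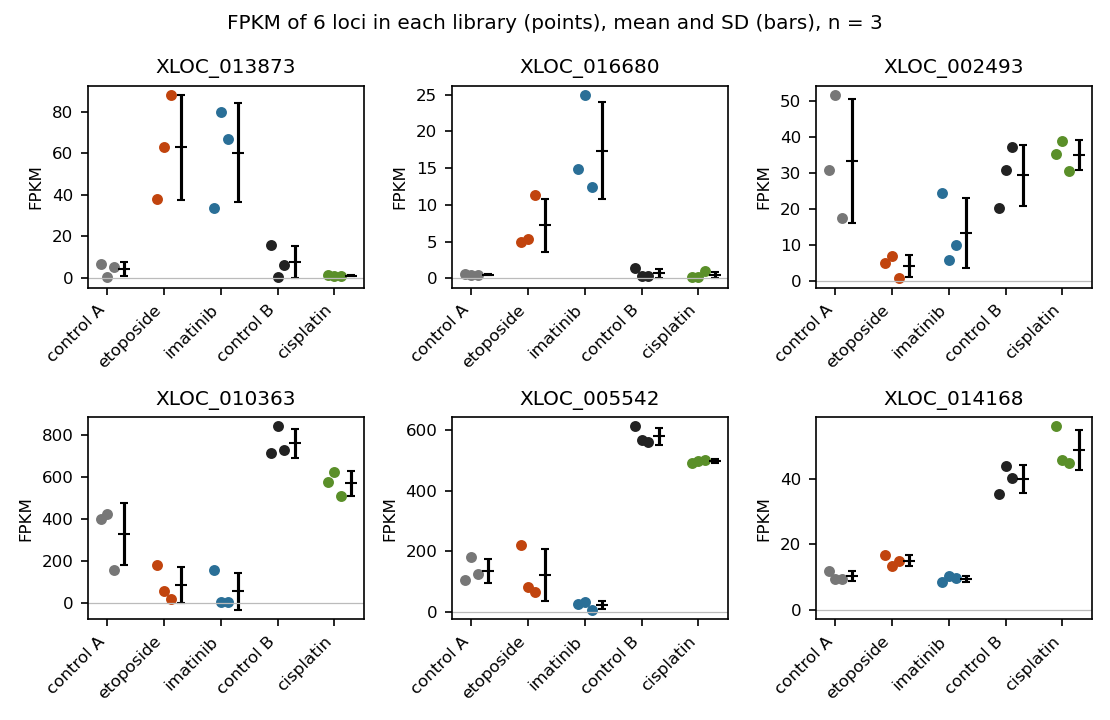
FPKM of 6 loci in each of the 15 libraries (points, coloured by group), with the mean and SD of each group (bars, n = 3). XLOC_013873 and XLOC_016680 are higher in the etoposide and imatinib libraries than in the controls, and XLOC_014168 lies near 40 to 49 FPKM in control B and cisplatin.

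With imatinib, 577 loci differed from both control sets, 124 higher and 453 lower (limma, adjusted p under 0.05 in each), with a median fold of 2.02 for the rises and 1.77 for the falls. XLOC_016680 (scaffold02921, 56256 to 58979) rose from 0.5301 ± 0.0717 FPKM in control A and 0.721 ± 0.6191 in control B to 17.4 ± 6.655 with imatinib (SD, n = 3). Its log2 fold change was 3.47 (SE 0.304, limma, adjusted p = 0.00252 and 0.000225). It passed under all 20 alternatives computed for it, whose fit of the groups compared held 9 libraries. In a fit of imatinib and control A alone it did not pass (limma, adjusted p = 0.0777). With etoposide, XLOC_016680 measured 7.217 ± 3.597 FPKM, also above every control library, so its higher values are not particular to imatinib. XLOC_013873, which also rose with etoposide, reached 60.23 ± 23.78 FPKM with imatinib. XLOC_010363 (scaffold01829, 88260 to 89477) fell to 57.08 ± 88.03 FPKM from 329.7 ± 147 and 761.5 ± 69.77, with 158.7 in imatinib 1 against 7.651 and 4.873 in the others. XLOC_005542 (scaffold01203, 18534 to 19216) fell to 20.96 ± 13.73 FPKM from 135.8 ± 39.68 in control A and 580.9 ± 27.91 in control B.
Against control A alone 1635 loci passed, 749 higher and 886 lower, and against control B alone 4196, 1139 higher and 3057 lower, or 1437 and 1993 after quantile normalization and 1601 and 1257 after median centring. The loci that passed against both sets were 196 higher and 385 lower after quantile normalization and 189 and 229 after median centring. Of all loci, 12.4% had imatinib values that did not overlap the 6 controls.
Here too the calls depended on the libraries fitted and on single libraries. Of the 577 loci, 8 passed with any of the 9 libraries left out in turn. A fit of the 9 libraries compared gave 76 loci, 67 of them among the 577. Imatinib with control B alone gave 5418, and imatinib with control A alone gave 2, with 2993 at an unadjusted p under 0.05. Those 2 were XLOC_017486 (scaffold03167, 2226 to 2386) and XLOC_002053 (scaffold00784, 14477 to 14671), named after their values were seen; XLOC_017486 was also the single locus that passed for etoposide in such a fit. XLOC_017486 and XLOC_002053 are short, at 160 and 194 bp, and have no spread within control A. Both were listed at 0 in all control A libraries, with 23.44 ± 1.559 and 26.68 ± 9.049 FPKM in imatinib, but XLOC_017486 had 45.28 ± 13.82 in control B and XLOC_002053 10.89 ± 7.513, and neither passed against control B (limma, adjusted p = 0.081 and 0.268). With all 15 libraries fitted, XLOC_002053 lost its call against control A without control A 2, imatinib 2 or imatinib 3 (limma, adjusted p = 0.0501, 0.0618 and 0.0546) and with library weights (0.0504). The 577 loci became 29 and 12 without imatinib 2 and 3, 880, 108 and 866 without control A 1, 2 and 3, and 318, 293 and 285 without control B 1, 2 and 3. The 1635 became 53 and 21 without imatinib 2 and 3, and 2470, 199 and 2672 without control A 1, 2 and 3; the 4196 became 2734, 2742, 2750 and 2376 without imatinib 2, imatinib 3, control B 2 and control B 3. XLOC_013873 lost its imatinib call without control A 2, imatinib 2 or imatinib 3, where its log2 fold change was 3.22, 3.35 and 3.47 against 3.59 with all libraries. XLOC_005542 lost it without control A 2 or imatinib 3 (-3.85 and -3.24 against -3.96), and XLOC_010363 without any of these, control A 1 or any control B library (-4.60 to -3.69 against -4.58). All 3 also lost it in the fit of the 9 libraries compared (limma, adjusted p = 0.0665, 0.0518 and 0.0843).

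**Figure D4:**
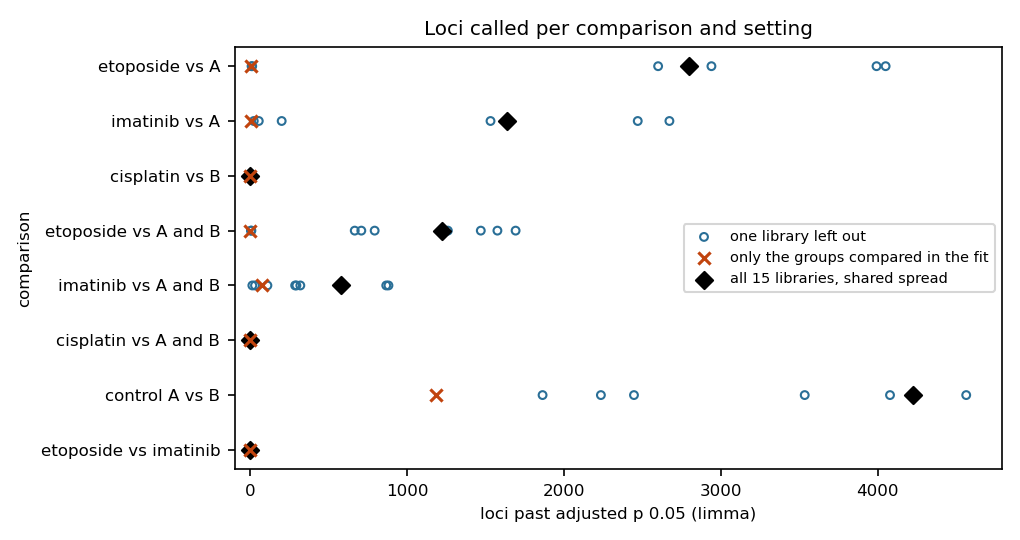
Number of loci past an adjusted p of 0.05 (limma) for 8 comparisons: all 15 libraries with a shared spread (diamonds), the groups compared alone (crosses) and each library left out in turn (circles). For etoposide against control A, the diamond is at 2797 and the cross at 1.

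Among the loci that differed from both control sets, 84 were higher with both drugs, where independent lists would share 1.49, and 154 were lower with both, where 25.1 would be shared; 0 moved in opposite directions. Simulated unchanged groups on the same controls gave shorter lists, 65.9 and 36.4 loci on average, which shared 15.8 on average and 25 at most. As a share of the imatinib list, the overlap was 41.2% observed (238 loci) and 43.3% in the simulated lists. Because the simulated lists were far shorter, this share does not decide whether the overlap exceeds that of unchanged groups. The fold changes against control A correlated across loci at 0.783, against 0.694 on average and 0.74 at most in simulated unchanged groups. Their covariance was 0.376 against 0.195. Loci are not independent replicates. With different control sets, the correlation across loci was 0.258 and 0.265.
Tested against each other, the drugs differed in 0 loci (limma, smallest adjusted p = 0.158), with 2289 at an unadjusted p under 0.05 where 905 are expected, so differences between them that are too small for this test are not excluded. The 95% interval of the difference lay within 2-fold for 64.8% of loci. The concentrations differed, 300 ng/L of etoposide and 2000 ng/L of imatinib.

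With cisplatin at 10 ng/L, 0 loci differed from both control sets and 0 from control B (limma, smallest adjusted p = 1), with 81 and 223 at an unadjusted p under 0.05. By chance, 905 would be expected against control B. The shared spread, a median residual SD of 0.304, was wider than the median SD within cisplatin (0.152) and control B (0.16), which makes the shared test conservative for these groups. Its libraries were as near to control B libraries, at a median MAD of 0.263, as to each other, also at 0.263. The 95% interval of the difference from control B lay within 2-fold for 74.5% of loci (13476), or 83.9% (15176) with the spread of these groups alone, and the median absolute log2 difference was 0.0976. Values of XLOC_014168 (scaffold02358, 32330 to 35022) were 48.93 ± 6.238 FPKM with cisplatin, 39.96 ± 4.211 in control B and 10.32 ± 1.459 in control A (SD, n = 3). XLOC_010968 (scaffold01894, 23360 to 29220) had 26.63 ± 4.279, 19.63 ± 4.175 and 3.065 ± 1.084 FPKM. Both differed from control A (limma, adjusted p = 4.81e-05 and 0.000178) and neither passed against control B (limma, adjusted p = 1 for each).
Against control A alone, 3853 loci passed, 2919 higher and 934 lower, or 1302 and 1340 after quantile normalization and 909 and 1539 after median centring; the median log2 difference of all loci was 0.245. The count was 769 in a fit of the 6 libraries compared, and 1776, 2073 and 1710 without cisplatin 1, 2 and 3.
Against control B, 674 loci had an unadjusted p under 0.05 in a fit of the 6 libraries, where 905 are expected, with 0 past the threshold, and a paired fit gave 0. Without cisplatin 3, 1 locus passed, XLOC_006894 (scaffold01364, 28807 to 31618), named after its values were seen: it had 5.84, 3.87 and 3.39 FPKM in control B, 3.76 in cisplatin 3, and under 0.001 in the other cisplatin libraries.

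Between drugs, cisplatin differed from etoposide in 4952 loci, 3797 higher and 1155 lower, and from imatinib in 4072, 3071 higher and 1001 lower (limma, adjusted p under 0.05). The splits were 2469 higher and 1896 lower, and 1771 and 1336, after quantile normalization, and 1852 and 2365, and 1123 and 1508, after median centring. The first count became 3078 without cisplatin 3 and 3051 without etoposide 3. The second became 2400, 2649 and 2181 without cisplatin 1, 2 and 3, and 2342 and 2493 without imatinib 2 and 3.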

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

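The tests of the distance between library sets and those of the depth of control A 1 and of short loci were chosen after the result was seen.

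Cisplatin differed from etoposide in 4952 loci and from imatinib in 4072, a difference between drug groups, while control A differed from control B in 4227. Cisplatin against control B gave 0 loci, 0% of the count against etoposide, which restates that control B libraries lie with cisplatin. Because control B is unexposed, cisplatin exposure cannot set it apart from control A, so it is argued against as the whole source. Scaling as the whole source is argued against by the 75.7% of the control A against control B count that was left after quantile normalization. Low depth of control A 1 is argued against too, as 96.5% of that count was left without it. A difference that is not the drug exists between the control sets, as both are unexposed and differed in 4227 loci. How far it accounts for the differences between drug groups stays open. The fold changes of cisplatin against etoposide correlated across loci with those of control B against control A at r = 0.664. That correlation restates the grouping the pattern was seen from, control A, etoposide and imatinib apart from control B and cisplatin, and decides nothing. The measures of distance differed on that grouping. The median MAD was 0.752 from etoposide to control A and 0.616 to control B, and 0.676 and 0.604 from imatinib. The highest Spearman correlations were 0.952 and 0.893 for etoposide, and 0.942 and 0.886 for imatinib, in the same order. Since the unexposed sets differ and what they differ in (day, brood, run or developmental stage) was not tested, drug comparisons across the sets cannot be read as drug effects.

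The second pattern is that few etoposide and imatinib calls against control A pass the threshold when etoposide 3, imatinib 2, imatinib 3 or control A 2 is left out (7, 53, 21, and 11 or 199 loci), or when each drug is fitted with control A alone (1 and 2), although without these libraries 4032, 3768, 3780, and 4377 or 3997 loci had an unadjusted p under 0.05, where 905 are expected, and 1045 to 1542 an adjusted p under 0.1 (limma). Without control A 1, 143% of the etoposide count and 151% of the imatinib count were found, so the calls do not need that library. Whether its low depth makes them depend on other single libraries is not decided, because those leave-outs and fits were not repeated without it. Loci of at least 500 bp gave 105% of the etoposide count and 101% of the imatinib count. They are 94.3% of the loci tested, so a large fall was hardly possible, and a part played by short loci is not decided. An effect carried by all 3 etoposide libraries came out in favour, with 25.3% of loci not overlapping control A, against 17.1% in the highest other split and 10% by chance, although a difference between groups for another reason would give the same. Unequal spread of the groups cannot be told apart from it: simulated unchanged groups with their own spread gave 5.29% as many calls (imatinib 5.46%), under the limit of 10% set beforehand, but that limit was wrong because the simulation drew loci independently while the fold changes of adjacent real loci correlate at 0.233 when under 1 kb apart and at 0.136 when farther, and the fit of these groups alone, which kept 1 call, changes the spread and the residual degrees of freedom together. Both may contribute.

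The third pattern is the likeness of the etoposide and imatinib fold changes against control A. With no control library in common, the lowest of the 6 covariances was 0.0657, above 0 and 17.5% of the covariance with shared libraries. This met the limit set beforehand for arguing against shared control A libraries as the whole source. That limit had no range for unchanged groups whose loci vary together. Deviations of same-numbered libraries of different groups correlated across loci from -0.38 to 0.5. The 6 pairings also reuse the same drug libraries, so the test does not decide. What stays open is a response common to both drugs, or a difference of the control A libraries from both drug groups for another reason; the design gives no test that parts these.

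Other splits of the same libraries were counted for each comparison. For etoposide against both control sets, 1 of 100 splits of the 9 libraries gave as many loci, the real one (1221, highest other 1213), and for imatinib 1 of 100 (577, highest other 70). That share is under 0.05, but it excludes only a grouping of the 9 libraries that ignores the control sets, which differ from each other in 4227 loci, and chance is not excluded for a drug beside a set: the split with 1213 loci put the 3 control B libraries in the place of the drug and mixed etoposide with control A, and the next highest gave 15. For cisplatin, 100 of 100 gave as many as the real 0, as any split must, so this share decides nothing. The highest other gave 3249, which points to a structure of the samples: it put the 3 control A libraries in the place of the drug. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave as many loci for etoposide against control A (2797, highest other 53) and control B (5193, 0), imatinib against control A (1635, 43) and control B (4196, 2), cisplatin against control A (3853, 1), control A against control B (4227, 1), cisplatin against etoposide (4952, 0) and cisplatin against imatinib (4072, 0). For cisplatin against control B (0, highest other 31) and etoposide against imatinib (0, highest other 0), 10 of 10 did, as any split must with a real count of 0. Of the splits of cisplatin and control B, 4 part all 3 same-numbered pairs, as the real one does, and the others of these gave 0 loci. The 31 came from the 6 splits that do not. That the same-numbered libraries are pairs is an assumption.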

How the results depend on the processing

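Library weights, loci of at least 500 bp, transcripts not summed and the paired fit of cisplatin and control B alone were chosen after seeing the data; the cause of each change was not tested unless the alternative itself shows it. No locus or transcript named in the text reversed its direction in the alternatives computed for it; those chosen after their values were seen were run without the 500 bp and summing alternatives. Another pseudocount, other filters, robust variance and loci of at least 500 bp kept each count within 1.5 times. A minimum of 2-fold, which leaves fewer loci by construction, gave 486 (both sets), 1072 (control A) and 2751 (control B) for etoposide, 170, 606 and 1985 for imatinib, 1628 for cisplatin against control A, 1918 between the control sets, and 2613 and 1854 for cisplatin against etoposide and imatinib. Fitting only the groups compared, with fewer libraries behind the spread, gave 0 and 1 for etoposide against both sets and control A, 76 and 2 for imatinib, 769 for cisplatin against control A and 1184 between the control sets; against control B it gave 4516 for etoposide and 5418 for imatinib, and for cisplatin against these drugs 4258 and 5332. The 6 controls as 1 group gave 2475 for etoposide and 1028 for imatinib. Library weights gave 0 and 1 for etoposide against both sets and control A, 7726 for imatinib against control B and 7553 for cisplatin against imatinib. Median centring gave 2448 for cisplatin against control A and 2631 against imatinib. Transcripts not summed gave 592 and 1408 for etoposide against both sets and control A, 314 and 1067 for imatinib, 2490 and 1 for cisplatin against control A and control B, and 2 for etoposide against imatinib. The correlation of etoposide and imatinib fold changes across loci, 0.798 against the mean of the control sets, was 0.258 and 0.265 when each drug had a different control set. With 1 library left out, the counts ran from 3 to 1691, 7 to 4051 and 3057 to 5051 for etoposide (both sets, control A, control B), 12 to 880, 21 to 2672 and 2376 to 3660 for imatinib, 1710 to 4309 and 0 to 1 for cisplatin against control A and control B (0 throughout against both), 1863 to 4565 between the control sets, 3051 to 4891 and 2181 to 3433 for cisplatin against etoposide and imatinib, and 0 throughout for etoposide against imatinib; a group left with 2 libraries was assumed to vary like the others. The replicate block moved no count by over 1.5 times: 962, 2216 and 4745 for etoposide, 451, 1293 and 3764 for imatinib, 0, 3274 and 0 for cisplatin, 3689 between the control sets, and 0, 4440 and 3511 between drugs. For cisplatin and control B, where the numbers were taken as pairs, the count of loci stayed at 0, also in the paired fit of these alone. There the transcript TCONS_00021064 lost its call with the replicate block (limma, adjusted p = 0.0876). In the other 9 of the 10 group pairs the numbers were not taken as pairs. Gene list tests and their alternatives were not run, as no list could be matched. Relative depth limits control A 1 most, at an estimated 15.5% of etoposide 2.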

Other observations

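At the level of single transcripts (26026 tested), 3 transcripts stood out in comparisons that gave 0 loci; they were picked after their values were seen. TCONS_00005347 of XLOC_002968 (scaffold00903, 47280 to 50174) had 0.291, 0.0197 and 0.365 FPKM with etoposide, against 75.3 ± 18.9 with imatinib, 103 ± 30.4 with cisplatin, 130 ± 83.4 in control A and 91.3 ± 18.7 in control B (SD, n = 3; limma, adjusted p = 4.27e-05 for etoposide against imatinib). The sum over the 3 transcripts of that locus was 784 ± 36.4 FPKM with etoposide and 727 ± 44.6 with imatinib. TCONS_00006135 of XLOC_003370 (scaffold00944, 4749 to 7010) had 5.53 ± 0.733 FPKM with imatinib (limma, adjusted p = 0.0188 for etoposide against imatinib), 1.22 in control B 3 and under 0.01 in the other 11 libraries. TCONS_00021064 of XLOC_011742 (scaffold01993, 55586 to 59244) was low in control B alone: it had 0.058 ± 0.0338 FPKM there, against 6.65 ± 2.21 with cisplatin (limma, adjusted p = 0.0157), 5.64 ± 2.03 in control A, 5.19 ± 1.57 with etoposide and 4.02 ± 0.766 with imatinib. The sum over that locus was 9.21 ± 1.39 in control B and 7.97 ± 0.166 with cisplatin. TCONS_00005347 passed in each of its 16 alternatives, TCONS_00006135 lost the call in 9 of 15 and TCONS_00021064 in 3 of 15, where the replicate block gave adjusted p of 0.0786 and 0.0876 (limma). How FPKM were divided between the transcripts of a locus was not tested.

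A hypothesis that neighbouring loci change together was tested on adjacent loci at least 1 kb apart. Their etoposide against control A fold changes correlated across loci at r = 0.136, above the highest of 1000 shuffles (0.054). The correlation was 0.151 for imatinib against control A and 0.291 for control A against control B, but also 0.144 for cisplatin against control B, where 0 loci passed, so it is not tied to loci that changed. Runs of at least 3 adjacent loci that fell or rose together with etoposide against both control sets held 109 loci in 33 runs, against at most 24 loci in shuffled order; for imatinib there were 19 loci in 6 runs, against at most 7. The longest runs, 5 loci for etoposide and 4 for imatinib, were no longer than the longest in shuffled order, also 5 and 4. Overlapping or split gene models may add to this.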
